A study of Mus musculus with 24 samples.

How the data were processed

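RNA sequencing values of 24 mouse lung macrophage and monocyte samples were analysed. Per the labels, cells came from perfused lungs of male C57BL/6 mice, red cells were lysed, doublets and dead cells were excluded, and the populations were sorted by flow cytometry. Libraries were made from total RNA with the NuGen Ovation FFPE kit and mouse ribosomal RNA oligonucleotides. Strand use is not given in the sources used here.

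The deposited table held 1 row per gene and 1 column of values per library. Per the submitters' processing notes, the authors checked reads with FastQC, aligned them to mm10 with TopHat2 version 2 and computed FPKM with Cufflinks 2.0.2. The header of the table named no unit, so the unit FPKM was taken from these notes, and the values did not contradict it. No count table was analysed here, so the values were taken as FPKM without recomputing them from reads. The loci in the table differed from GRCm38, with 4218 of 32917 matched genes overlapping their GENCODE M21 position and 271 loci past the last gene of their chromosome. Positions were therefore taken from GENCODE M21 (GRCm38) by Ensembl identifier. The design text of the series gives the name of the 3-week group to the MacB3 samples of 2 weeks, and the sample titles were followed.

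The table held 37979 genes. Of these 14133 were at 0 in every library, and 255 symbols occurred more than 1 time and were kept apart by Ensembl identifier. Library sums were 1880236 to 4868372 FPKM. Genes annotated as miRNA, under 2 spellings of the type, made up 43.7% to 75.1% of the sum and protein-coding genes 10.4% to 27.8%. FPKM values of different libraries were not rescaled in the analysis reported, a choice made before the data were examined, and 2 rescalings were tried as alternatives. Absolute depth could not be read from FPKM, and the relative depth of each library was estimated from the smallest steps between values of low genes. In 688 genes, 14 of them protein coding, a library was at exactly 0 in a group with a mean of at least 20 FPKM. A group at 0 in all 3 libraries was reported as listed, without a fold. Genes with near-identical copies (Ly6c2, Ear1, Ear2, the hemoglobin genes, Ifi204 and Ifi205) can split or share reads, so their levels are uncertain.

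Values were transformed to log2(FPKM + 1). Genes with a mean of at least 1 FPKM in at least 1 group were tested, which left 17156. All 24 libraries were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, 16 residual degrees of freedom and empirical Bayes moderation with a trend in mean level. The 12 pairwise comparisons and the interaction were contrasts of this fit. P values were adjusted over all genes by the Benjamini-Hochberg method within each comparison. A gene was called when its adjusted p was under 0.05 and its fold at least 2. The 3 libraries of a group were treated as replicates from independent experiments. Replicate numbers were not used to pair samples across groups, and a block on replicate number was tried as an alternative.

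Gene lists were written from general knowledge before the data were examined, as were the design, the comparisons, the thresholds, the rule for naming genes and the alternatives. They held 38 lists with 706 entries, of which 703 matched a gene. The 35 lists with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists. Counts of members called are given over all genes and, for main lists, also after adjustment over the members of the list alone. No list called in the report had a median or mean log2 fold change opposite in sign to its test.

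Genes were named by a rule, and some that met it are not reported here. In each comparison the rule took the 6 highest and 6 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 20 FPKM in the higher group, replicates that did not overlap between groups and a proper symbol. Up to 4 members with the smallest adjusted p from each of the 5 called lists with the smallest p were added, and Siglecf, Itgax, Itgam, Ly6g, Fcgr1, Ccr2, Cx3cr1, Csf1r and Arg1 were named throughout. Members of the lists for other cell types could be named wherever they passed. Symbols starting with Snor were left out by a match to upper and lower case, so SNORA84 stayed in. Genes named in a comparison beyond this rule, because another comparison named them, were chosen after their values were seen.

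The method was tested on simulated data made from the group means and the spread of each gene, with the compared groups set equal and then 200 of 17156 genes changed. In a contrast with the groups of MacA-2wk and MacA-N, 41 of 100 genes with a 2-fold change and 85 of 100 with a 4-fold change were recovered at an adjusted p under 0.05, with 6 false calls (4 with the fold minimum). For MacB2-3wk and MacB2-N, 22 and 82 of 100 were recovered, with 8 false calls (7 with the minimum). With genes drawn as uncorrelated, the moved list and 0 others were called in both.

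The alternatives were no fold minimum, a pseudocount of 0.1 FPKM, no filter on low values, a filter at 5 FPKM, quantile normalization, upper-quartile scaling, array weights, a block on replicate number, a fit of only the groups compared, leaving out each library of the groups compared, and the estimated correlation for lists. A fit of protein-coding genes only was added after the data were seen. Where a group was left with 2 libraries, its spread was pooled with the other groups. Every split of the 6 libraries of a pairwise comparison into 3 and 3 was refitted, and 100 regroupings were drawn for the interaction. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Raw reads, splicing and isoforms were not analysed here.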

Results

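RNA sequencing values were analysed for 24 libraries from macrophages and monocytes sorted out of mouse lung, in 8 groups of 3 libraries. Naive lungs gave MacA-N (sorted as SiglecF+ and CD11c+), MacB1-N (CD11b+, Ly6G-, CD64 low, CD11c+) and MacB2-N (CD11b+, Ly6G-, CD64 intermediate, CD11c-). Lungs carrying orthotopic Lewis lung carcinoma cells with luciferase gave MacA-2wk, MacB2-2wk and MacB3-2wk at 2 weeks, and MacB2-3wk and MacB3-3wk at 3 weeks, where MacB3 was CD11b+, Ly6G-, CD64 high and CD11c+. Per the labels, the 3 libraries of a group came from 3 independent experiments and each held cells pooled from 3 to 5 mice, so they were treated as replicates (n = 3 per group in every comparison). Naive samples used all lobes and tumour samples used the left lobe with the tumour, so every contrast of tumour against naive also compared these 2 kinds of tissue. All MacA libraries were run on lane 1 and the MacB libraries on lanes 2, 3 and 7, so population and lane could not be separated in any contrast of MacA with MacB.

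The values covered 37979 genes, of which 14133 were at 0 in every library and 17156 reached a mean of 1 FPKM in at least 1 group and were tested. Each library had 15599 to 18522 genes above 0 and 12503 to 14324 genes at 1 FPKM or more. The steps between low values put relative depth between 0.521 (MacB2-2wk replicate 3) and 1 (MacA-N replicate 1), and absolute depth was unknown. Library sums ran from 1880236 to 4868372 FPKM, with 43.7% to 75.1% of the sum from miRNA genes (a mean of 1179970 FPKM for Mir5105) and 10.4% to 27.8% from protein-coding genes. Levels are given as mean ± SD in FPKM with n = 3, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the fold of genes with low levels.

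Transcripts of the sorting markers followed the gates in most groups. Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531, GRCm38) was at 231 ± 70.0 FPKM in MacA-N and 146 ± 23.1 in MacA-2wk, and at 5.25 FPKM or less in each MacB group. Itgax, which encodes CD11c (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657), was at 103 ± 11.2 FPKM in MacB1-N, 72.3 ± 21.6 in MacB3-2wk and 71.2 ± 8.84 in MacB3-3wk, against 7.33 ± 1.66 in MacB2-N, 11.2 ± 1.81 in MacB2-2wk and 12.01 ± 1.92 in MacB2-3wk. Itgam, which encodes CD11b (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), was at 2.30 ± 2.08 FPKM in MacA-N and between 213 ± 51.1 (MacB2-3wk) and 300.0 ± 59.5 (MacB3-2wk) in the MacB groups. Fcgr1, which encodes CD64 (ENSMUSG00000015947, chromosome 3, 96282909 to 96293969), was lowest in MacB1-N at 9.54 ± 1.12 FPKM and highest in MacB3-2wk at 181 ± 6.86. Ly6g was listed at 0 in all 24 libraries, so its transcript could not show whether the Ly6G- gate held.

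**Figure D1:**
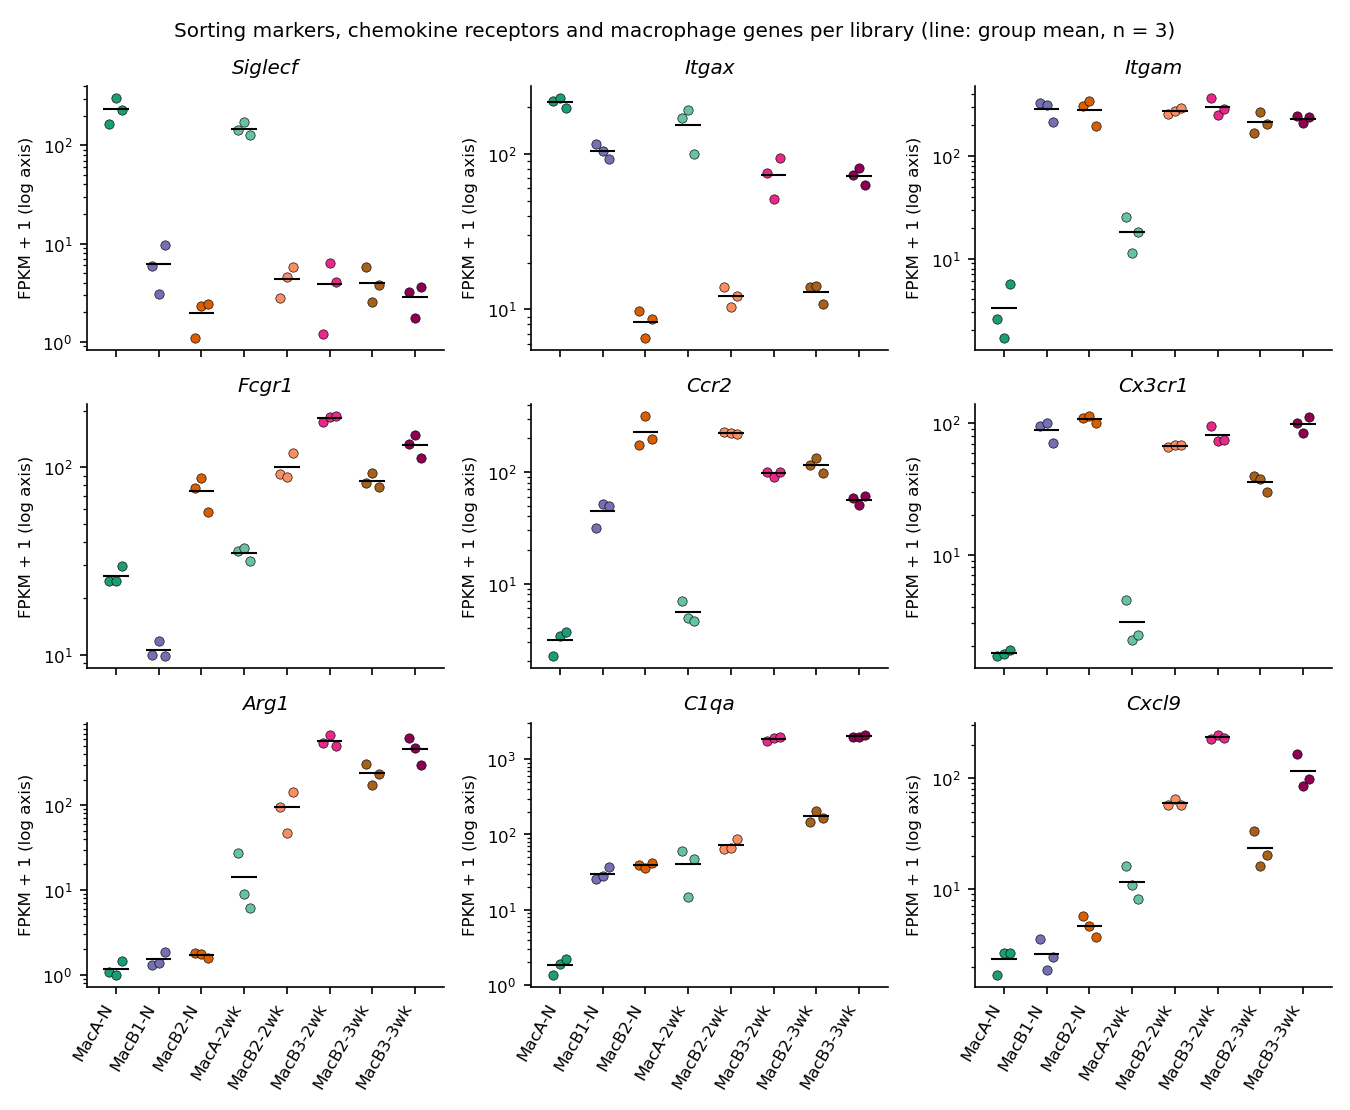
Levels of 9 genes (FPKM + 1, log axis) in each library of the 8 groups, where points are libraries and lines are group means. Siglecf averaged 231 FPKM in MacA-N and 146 in MacA-2wk, and C1qa averaged 1864 in MacB3-2wk and 2048 in MacB3-3wk.

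Libraries grouped by population. The median correlation of log2 values was 0.911 within groups (0.843 to 0.933) and 0.830 between groups, and 22 of 24 libraries correlated best with a library of their own group. MacA-2wk replicates 2 and 3 correlated best with MacA-N. MacA-2wk replicate 3 lay apart from the other MacA libraries, with a mean log2(FPKM + 1) of 4.51 over the fibroblast list against 2.21 and 2.27 in replicates 1 and 2. MacB2-N replicate 3 had a mean of 5.30 over the endothelial list against 3.64 and 3.62 in replicates 1 and 2.

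**Figure D2:**
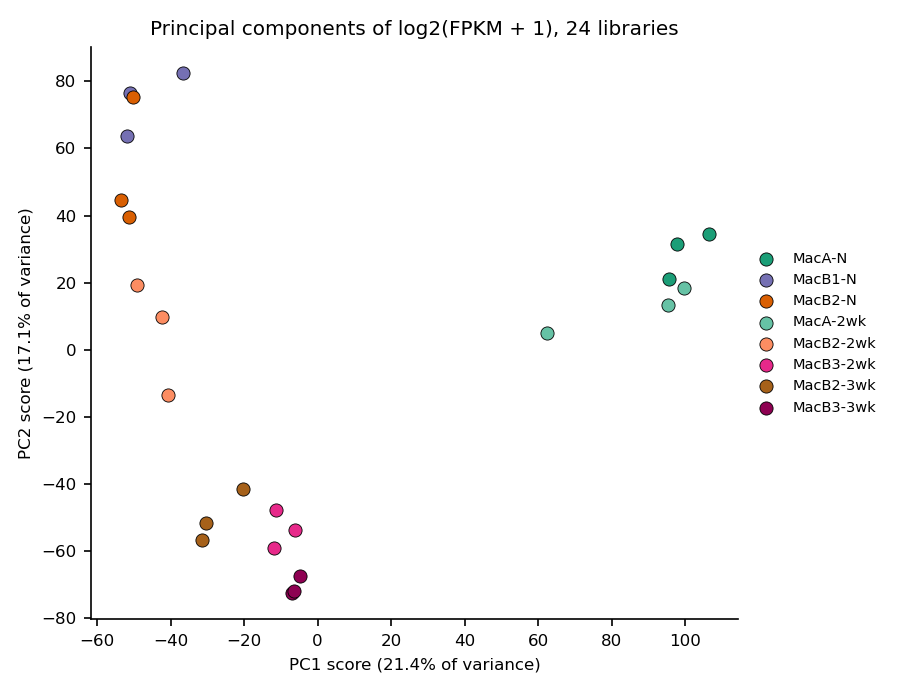
Principal component 1 (21.4% of variance) against component 2 (17.1%) for 24 libraries on log2(FPKM + 1), with points as libraries coloured by group. MacA libraries lay at the right, and MacA-2wk replicate 3 was the MacA library nearest to the MacB groups.

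MacB1-N was set against MacA-N to ask how this CD11c+ population of the naive lung differed from the SiglecF+ one. MacB1-N had 2572 genes higher and 1495 lower. Among the highest were Plac8 (199 ± 56.4 against 0.413 ± 0.432 FPKM, log2 fold change 7.16), Pglyrp1, which encodes a peptidoglycan-binding protein (613 ± 228 against 2.60 ± 1.41, 7.42), and Fyb, a leukocyte adaptor (523 ± 160.0 against 2.02 ± 0.789, 7.42). Fabp1, a fatty acid binding protein, was at 10.5 ± 11.2 FPKM against 959.9 ± 521 in MacA-N (-6.86), and Atp6v0d2, a proton pump subunit, at 10.8 ± 13.2 against 573 ± 54.0 (-6.21). Ear1 (-6.16), Wfdc21 (-6.28), F7 (-6.02) and the lipid droplet gene Cidec (-6.05) completed the 6 lowest.

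In the alveolar macrophage list 0 of 20 measured members were higher, 18 lower and 2 not called (0 and 18 adjusted over the list alone), with adjusted p = 2.43e-20, and adjusted p = 0.0217 with an estimated correlation. Its members included the sterol transporter gene Abcg1 (70.4 ± 17.2 against 865 ± 73.1 FPKM), Perp (1.77 ± 1.89 against 55.3 ± 8.64) and Kcnip4 (0.348 ± 0.328 against 10.1 ± 2.95). Fatty acid handling genes were lower (adjusted p = 1.35e-08, and adjusted p = 0.00802 with an estimated correlation). Lysosome genes were lower (adjusted p = 2.38e-10, but adjusted p = 0.0652 with an estimated correlation), with 20 of 30 measured members lower, among them Ctsd (142 ± 71.1 against 2261 ± 377 FPKM). Nonclassical monocyte genes were higher (adjusted p = 1.34e-08, but adjusted p = 0.0508 with an estimated correlation), with 12 of 14 higher, including Emr4 (99.98 ± 21.5 FPKM), Ace (745 ± 158) and Pou2f2 (149.7 ± 46.6). Interferon-stimulated genes were higher (adjusted p = 7.93e-08, but adjusted p = 0.0788 with an estimated correlation). Irf7 (log2 fold change 3.77), Oas3 (2.99), Oasl2 (2.79) and Cmpk2 (2.38) were examples.

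Cx3cr1 (88.5 ± 15.9 against 0.770 ± 0.0974 FPKM), Ccr2 (43.4 ± 11.4 against 2.10 ± 0.775) and the growth factor receptor gene Csf1r (524 ± 141 against 71.4 ± 3.74) were higher in MacB1-N. Arg1 was at 0.515 ± 0.301 and 0.176 ± 0.240 FPKM. Markers of other cell types were also higher in MacB1-N, with 15 of 16 endothelial genes (adjusted p = 9.69e-05, but adjusted p = 0.302 with an estimated correlation) and 14 of 15 fibroblast genes (adjusted p = 1.27e-04, but adjusted p = 0.277 with an estimated correlation). The test was limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, as for every comparison. Lane and population were confounded here, and quantile normalization changed the split to 1930 higher and 2161 lower with a shift of -0.147 in the median log2 fold change.

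**Figure D3:**
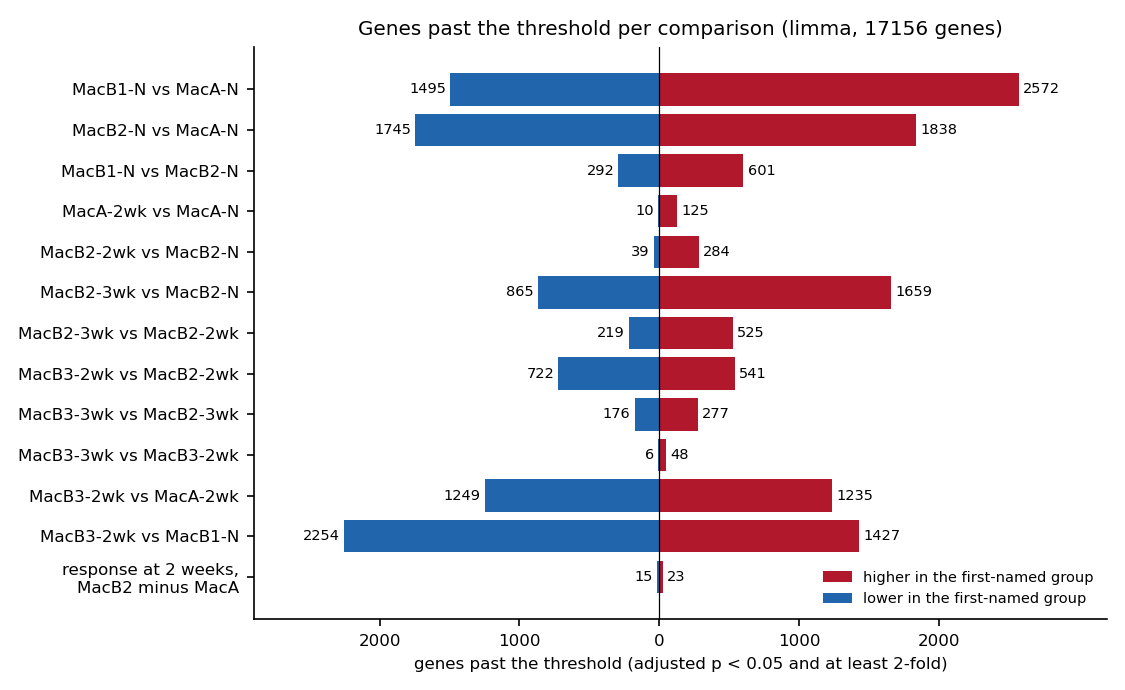
Number of genes called higher (right) and lower (left) in the group named at the start of each of the 12 pairwise comparisons and in the interaction. Counts ran from 38 for the interaction to 4067 for MacB1-N against MacA-N.

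MacB2-N was set against MacA-N to ask the same of the CD11c- population. MacB2-N had 1838 genes higher and 1745 lower. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), whose product marks classical monocytes, was at 2503 ± 461 FPKM against 2.57 ± 0.972 (log2 fold change 9.48), Plac8 at 797 ± 226 against 0.413 ± 0.432 (9.15) and Ifitm6 at 662 ± 247 against 1.22 ± 1.40 (8.35). Fabp1 (-9.03), Ear1 (-8.01), Cidec (-7.67) and Wfdc21 (-7.34) were lower. Mcoln3, which encodes an endolysosomal channel, was listed at 0 in all 3 MacB2-N libraries and at 161, 159 and 157 FPKM in MacA-N. The small RNA gene AF357399 was listed at 0 in all 3 MacB2-N libraries and at 191, 97.2 and 567 FPKM in MacA-N, and its call was lost without MacA-N replicate 3 (adjusted p = 0.0739, limma) and without MacB2-N replicate 1 (0.0509), within a range of 0.00218 to 0.0739 over all alternatives.

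All 20 of 20 measured alveolar macrophage genes were lower, with Plet1 at 10.7 ± 0.531 against 1909 ± 667 FPKM and Abcg1 at 29.1 ± 4.11 against 865 ± 73.1 (adjusted p = 7.09e-25, and adjusted p = 0.00453 with an estimated correlation). Interferon-stimulated genes were higher (adjusted p = 1.04e-21, and adjusted p = 0.00453 with an estimated correlation), with 23 of 25 measured members higher. Examples were the antiviral genes Oas3 (5.17) and Oasl2 (5.44), the transcription factor gene Irf7 (549.9 ± 208 against 8.01 ± 0.195 FPKM) and Ifi204 (149 ± 11.3 against 8.13 ± 0.512). Cell cycle genes were lower in MacB2-N, where 0 of 30 measured members were higher, 26 lower and 4 not called (0 and 26 adjusted over the list alone), with adjusted p = 1.22e-15, and adjusted p = 0.0221 with an estimated correlation. Ube2c was at 1.47 ± 0.871 FPKM against 33.5 ± 7.84, Tpx2 at 0.679 ± 0.418 against 38.8 ± 3.85, Ccnb2 at 0.0853 ± 0.148 against 9.76 ± 2.10 and the replication gene Mcm3 at 5.91 ± 0.189 against 30.6 ± 5.67.

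Classical monocyte genes were higher (9 of 12, adjusted p = 2.02e-11, and adjusted p = 0.00238 with an estimated correlation). F13a1 was at 153 ± 33.6 against 0.344 ± 0.205 FPKM and the chemokine receptor gene Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557) at 229 ± 75.4 against 2.10 ± 0.775. Fatty acid handling genes were lower (17 of 28, adjusted p = 3.54e-11, and adjusted p = 0.00206 with an estimated correlation). Fcgr1 (1.48), Cx3cr1 (5.93) and Csf1r (2.85) were higher and Itgax (-4.71) and Siglecf (-6.95) lower. Arg1 was at 0.715 ± 0.124 FPKM in MacB2-N. These differences between MacA and MacB were confounded with lane.

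MacB1-N was set against MacB2-N to ask what separated the CD11b+ populations of the naive lung. MacB1-N had 601 genes higher and 292 lower. The genes for the chemokines Ccl22 (266 ± 41.6 against 0.577 ± 0.856 FPKM, log2 fold change 7.52) and Ccl17 (362 ± 78.6 against 2.34 ± 2.16, 7.04), both ligands of Ccr4, were the highest by fold, and Mgl2 (268 ± 32.6, 5.96), Klrb1b (109 ± 21.2, 5.85) and the actin-bundling gene Fscn1 (56.3 ± 1.82, 4.63) followed. The small RNA gene SNORA84 was listed at 0 in all 3 MacB2-N libraries and at 169, 33.4 and 228 FPKM in MacB1-N, and its call was lost when any single library of these 2 groups was left out (adjusted p 0.0294 to 0.144 over the alternatives, limma). Ly6c2 (50.1 ± 19.2 against 2503 ± 461 FPKM, -5.66), Cd177 (-4.42), Mmp8 (-3.96), F13a1 (-3.82) and Ifi205 (-3.75) were among the lowest.

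Classical monocyte genes were lower in MacB1-N (10 of 12, adjusted p = 1.42e-22, and adjusted p = 8.07e-05 with an estimated correlation). An example was Ccr2 (43.4 ± 11.4 against 229 ± 75.4 FPKM). Interferon-stimulated genes were lower, where 0 of 25 measured members were higher, 17 lower and 8 not called (0 and 19 adjusted over the list alone), with adjusted p = 3.30e-28, and adjusted p = 0.00221 with an estimated correlation. Isg15 was at 15.8 ± 1.95 FPKM against 94.8 ± 11.97, Oasl2 at 33.2 ± 9.86 against 212 ± 45.6, Oas3 at 11.3 ± 6.09 against 51.6 ± 13.4 and Ifi204 at 30.7 ± 7.49 against 149 ± 11.3. Cell cycle genes were higher (14 of 30, adjusted p = 1.51e-10, but adjusted p = 0.0633 with an estimated correlation). Among them were Ube2c (2.61), Top2a (2.05), Mcm5 (1.29) and Mcm6 (1.56). Nonclassical monocyte genes were higher (7 of 14, adjusted p = 2.24e-08, but adjusted p = 0.0633 with an estimated correlation). Cd300e was at 208 ± 54.3 against 14.6 ± 5.27 FPKM and Cd36 at 137 ± 28.2 against 46.1 ± 19.9. Alveolar macrophage genes were higher (6 of 20, adjusted p = 1.37e-06, but adjusted p = 0.160 with an estimated correlation), and the change of their mean went from 1.18 to 0.76 without MacB1-N replicate 3. Pparg (log2 fold change 1.98), Mrc1 (2.01) and Fabp4 (2.34) were examples. Markers of other cell types were higher as lists in MacB1-N, with 4 of 13 dendritic cell genes higher and 1 lower (adjusted p = 0.00100), 3 of 8 NK cell (0.00499), 4 of 11 B cell (0.00204) and 1 of 14 T cell genes (4.60e-05), but adjusted p = 0.0633 with an estimated correlation for each. Fibroblast genes (1 of 15, adjusted p = 4.48e-04) and endothelial genes (0 of 16, 3.29e-04) were higher as lists too, but adjusted p = 0.430 with an estimated correlation for both. Whether such cells added to Ccl17, Ccl22 and Fscn1 was not tested. Itgax was higher (3.66) and Fcgr1 lower (-2.80), while Itgam was at 286 ± 62.6 and 280.5 ± 75.1 FPKM and Csf1r at 524 ± 141 and 523 ± 58.8. Quantile normalization changed the split to 423 higher and 422 lower with a shift of -0.111 in the median, 1393 genes passed without MacB2-N replicate 3, and 268 passed when only these 2 groups were fitted, which lost the calls of Oas3, Ube2c, Top2a, Mcm5, Mcm6, Cd36, Pparg and Mrc1.

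MacA-2wk was set against MacA-N to ask how the SiglecF+ population differed in lungs with a tumour at 2 weeks. In MacA-2wk 125 genes rose and 10 fell. The complement genes C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803; 0.836 ± 0.442 to 39.6 ± 23.2 FPKM, log2 fold change 4.27), C1qc (0.364 ± 0.468 to 30.4 ± 12.2, 4.49) and C1qb (2.10 ± 0.588 to 43.3 ± 25.7, 3.64) rose, as did AA467197 (0.932 ± 1.16 to 29.5 ± 11.5, 4.06). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes an arginine-degrading enzyme, rose from 0.176 ± 0.240 to 13.1 ± 11.5 FPKM (3.30). Serpinf1 (3.84, 5.77 and 82.9 FPKM in replicates 1 to 3), Gja1 (5.24, 5.41 and 96.2) and Col3a1 (13.7, 8.52 and 98.7) rose with most of the signal in replicate 3, and the call of Col3a1 was lost without that library (adjusted p 0.00598 to 0.548 over the alternatives, limma). Without MacA-N replicate 1, and again without replicate 2, the calls of Serpinf1 (adjusted p 6.15e-04 to 0.571 over the alternatives, limma), Gja1 (0.00486 to 0.59996) and Col3a1 were lost, the latter 2 also without replicate 3. Entpd1, which encodes an ATP-degrading ectoenzyme, fell from 174 ± 11.3 to 66.9 ± 10.4 FPKM (-1.37), and Sap30bp (-1.40) and Rnd3 (-1.08) fell, calls lost without 4 and 2 of the 6 libraries, left out in turn, MacA-N replicate 2 among them (adjusted p over the alternatives 0.0115 to 0.377 and 8.06e-04 to 0.416, limma).

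In the interferon-stimulated list 14 of 25 measured members rose, 0 fell and 11 were not called (16 and 0 adjusted over the list alone), with adjusted p = 3.00e-33, and adjusted p = 0.00187 with an estimated correlation. Oas3 rose from 0.435 ± 0.0401 to 7.22 ± 1.70 FPKM, Oasl2 from 4.26 ± 2.64 to 25.0 ± 5.43, Ifit2 from 0.589 ± 0.168 to 4.93 ± 0.710 and the chemokine gene Cxcl9 from 1.36 ± 0.568 to 10.7 ± 4.09. Interstitial and monocyte-derived macrophage genes rose as a list (4 of 17 members, adjusted p = 5.08e-13, and adjusted p = 0.00223 with an estimated correlation). Complement genes rose as a list (5 of 22 members, adjusted p = 2.76e-05, and adjusted p = 0.0233 with an estimated correlation). An example was C3ar1 (2.58). The alveolar macrophage list fell as a group with no single member called (adjusted p = 2.76e-05, but adjusted p = 0.219 with an estimated correlation, median log2 fold change -0.55). The change of its mean was -0.49, and -0.21 without MacA-2wk replicate 3.

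Itgam rose from 2.30 ± 2.08 to 17.3 ± 7.11 FPKM (2.58). The rise of Itgam, C3ar1, Cxcl9, Arg1 and the C1q genes would need 1.64% to 5.01% of carried-over MacB cells. Oasl2 needed 9.68%, Oas3 14.3% and Ifit2 17.9%. Carry-over could have raised the interstitial macrophage, complement and, at least in part, interferon lists. Siglecf (231 ± 70.0 and 146 ± 23.1), Itgax (214 ± 16.1 and 152.1 ± 48.1), Csf1r (71.4 ± 3.74 and 72.4 ± 27.6) and Spp1 (156 ± 6.67 and 443 ± 237) were not called. Extracellular matrix genes rose as a list with 1 of 27 members called (adjusted p = 4.26e-05, but adjusted p = 0.219 with an estimated correlation), and fibroblast genes did the same with 1 of 15 (adjusted p = 0.00321, but adjusted p = 0.511 with an estimated correlation). Without MacA-2wk replicate 3 the change of the mean went from 0.83 to 0.35 for matrix genes and from 0.85 to 0.09 for fibroblast genes. When only these 2 groups were fitted, 4 genes passed and every call named here was lost, such as C1qa (adjusted p 2.81e-10 to 0.276 over the alternatives, limma) and Oas3 (8.83e-07 to 0.114).

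MacB2-2wk was set against MacB2-N to ask how the CD11c- population differed with a tumour at 2 weeks. In MacB2-2wk 284 genes rose and 39 fell. Arg1 rose from 0.715 ± 0.124 to 93.3 ± 47.0 FPKM (log2 fold change 5.65), the protease genes Ctsk from 0.771 ± 0.667 to 51.4 ± 27.3 (4.79), Mmp9 from 19.7 ± 5.98 to 436 ± 184 (4.35) and Mmp12 from 0.847 ± 0.0390 to 37.5 ± 33.5 (4.03). Spp1, which encodes osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 5.40 ± 4.92 to 101 ± 38.0 FPKM (4.17) and AA467197 from 2.20 ± 1.11 to 78.7 ± 24.4 (4.66). Tmcc3 (93.1 ± 36.0 to 28.9 ± 13.4, -1.68), Pitpnm1 (-1.30), Ccdc88c (-1.29), the autophagy gene Atg2a (-1.25), Rasgef1b (-1.16) and Chkb (-1.03) fell, and each of these 6 calls was lost without MacB2-2wk replicate 3 and without MacB2-N replicate 1, and 4 of them also without other libraries. Their adjusted p over the alternatives (limma) were 0.00161 to 0.315 for Tmcc3, 0.00485 to 0.320 for Pitpnm1, 0.00896 to 0.135 for Ccdc88c, 0.0104 to 0.277 for Atg2a, 0.0243 to 0.221 for Rasgef1b and 0.00204 to 0.154 for Chkb.

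In the cell cycle list 10 of 30 measured members rose, 0 fell and 20 were not called (13 and 0 adjusted over the list alone), with adjusted p = 2.75e-15, and adjusted p = 0.0430 with an estimated correlation. Ube2c rose from 1.47 ± 0.871 to 25.1 ± 6.47 FPKM, Top2a from 2.19 ± 1.39 to 13.5 ± 0.850, Plk1 from 0.0488 ± 0.0440 to 3.66 ± 0.798 and Ccnb2 from 0.0853 ± 0.148 to 3.81 ± 1.83. Matrix remodelling genes rose (10 of 22, adjusted p = 2.06e-12, and adjusted p = 0.00415 with an estimated correlation). Mmp14 (log2 fold change 3.14) and Plau (1.91) were examples. Extracellular matrix (3 of 27, adjusted p = 4.95e-06, but adjusted p = 0.243 with an estimated correlation) and fibroblast genes (2 of 15, adjusted p = 0.00105, but adjusted p = 0.422 with an estimated correlation) also rose as lists. The median of 38 transcripts that tumour tissue could have contributed was 5.61 to 7.80 FPKM in MacB2-2wk libraries. It was 0.709 to 2.56 in MacB2-N but 3.60 to 4.42 in MacB1-N, also naive. Whether such tissue added to the matrix remodelling and cell cycle rises was not tested. Chemokine genes rose (7 of 23, adjusted p = 1.81e-11, and adjusted p = 0.00683 with an estimated correlation). Cxcl9 went from 3.71 ± 0.983 to 59.0 ± 3.92 FPKM, Cxcl10 from 101 ± 9.30 to 1105 ± 318, both ligands of Cxcr3, Ccl5 from 23.3 ± 11.7 to 112 ± 10.0 and Cxcl3 from 2.45 ± 1.62 to 50.5 ± 17.8. Glycolysis and hypoxia genes rose (5 of 25, adjusted p = 5.83e-08, but adjusted p = 0.0687 with an estimated correlation). Examples included Ldha (1.16), Bnip3 (2.07), Ero1l (1.33) and Egln3 (2.37, lost without 5 of the 6 libraries in turn, all but MacB2-2wk replicate 2, adjusted p 0.00244 to 0.163 over the alternatives by limma). Nonclassical monocyte genes fell as a list with no member called (adjusted p = 3.15e-07, but adjusted p = 0.0687 with an estimated correlation). Itgam (274 ± 15.8 FPKM), Ccr2 (223 ± 2.74), Fcgr1 (98.8 ± 16.3) and Cx3cr1 (66.4 ± 0.924) were not called. Quantile normalization changed the split to 209 risen and 71 fallen, and 136 genes passed without MacB2-2wk replicate 3. When only these 2 groups were fitted 37 passed, and every call named here was lost but those of Arg1, AA467197, Mmp9, Plk1, Cxcl9 and Cxcl10.

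MacB2-3wk was set against MacB2-N to ask the same at 3 weeks. In MacB2-3wk 1659 genes rose and 865 fell. Arg1 rose from 0.715 ± 0.124 to 237 ± 65.1 FPKM (log2 fold change 7.08), Mmp12 from 0.847 ± 0.0390 to 191 ± 97.7 (6.58) and Cxcl3 from 2.45 ± 1.62 to 274 ± 172 (6.12). Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220), which encodes a secreted growth factor and belonged to a group of transcripts that tumour tissue could have contributed, rose from 0.204 ± 0.353 to 151 ± 24.2 FPKM (7.00). The small RNA gene U5 (ENSMUSG00000064881) was listed at 0 in all 3 MacB2-N libraries and at 329, 1095 and 443 FPKM in MacB2-3wk, and Rny1 rose from 721 ± 645 to 8450 ± 4126 FPKM, a call lost without MacB2-N replicate 3 or MacB2-3wk replicate 1 (adjusted p 0.00521 to 0.257 over the alternatives, limma). The secretory cell gene Scgb1a1 fell from 6967 ± 3768 to 619 ± 122 FPKM (-3.32), Scgb3a2 from 138 ± 87.8 to 15.4 ± 15.1 (-3.28), Cyp2f2 from 90.5 ± 44.1 to 4.47 ± 1.72 (-4.00) and the hemoglobin genes Hbb-bs from 153 ± 101 to 5.10 ± 4.12 (-4.68) and Hba-a2 from 22.9 ± 22.1 to 0.138 ± 0.239 (-3.69). Without MacB2-N replicate 1, and again without MacB2-3wk replicate 1 or 3, the calls of Scgb1a1 (adjusted p 0.00172 to 0.0706 over the alternatives, limma), Scgb3a2 (0.00107 to 0.0945), Hbb-bs (0.00235 to 0.0726) and Hba-a2 (0.00232 to 0.145) were lost, Scgb1a1 and Hba-a2 also without MacB2-N replicate 2 and Hba-a2 without MacB2-3wk replicate 2.

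In the cell cycle list 25 of 30 measured members rose, 0 fell and 5 were not called (25 and 0 adjusted over the list alone), with adjusted p = 1.69e-20, and adjusted p = 0.0207 with an estimated correlation. Ube2c rose from 1.47 ± 0.871 to 81.6 ± 17.4 FPKM, Top2a from 2.19 ± 1.39 to 60.01 ± 8.28, Plk1 to 11.99 ± 4.13 and Ccnb2 to 11.4 ± 1.63. Glycolysis and hypoxia genes rose (14 of 25, adjusted p = 7.77e-11, and adjusted p = 0.0265 with an estimated correlation). Ldha (log2 fold change 1.93), Bnip3 (3.63), Ero1l (2.56) and the oxygen sensor gene Egln3 (4.14) were examples. Matrix remodelling genes rose (12 of 22, adjusted p = 3.45e-08, and adjusted p = 0.0207 with an estimated correlation). Mmp14 went from 3.73 ± 1.47 to 129 ± 33.9 FPKM and Plau from 1.39 ± 0.936 to 20.7 ± 1.80. Nonclassical monocyte genes fell (11 of 14, adjusted p = 7.77e-11, and adjusted p = 0.0238 with an estimated correlation). Ace went from 286 ± 98.3 to 44.8 ± 7.21 FPKM and Spn from 119 ± 41.96 to 19.9 ± 2.85. Chemokine genes rose (13 of 23, adjusted p = 2.37e-06, and adjusted p = 0.0392 with an estimated correlation).

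Extracellular matrix genes rose (13 of 27, adjusted p = 3.89e-07, but adjusted p = 0.210 with an estimated correlation). Spp1 rose from 5.40 ± 4.92 to 354 ± 105 FPKM, and so did 3 genes whose transcripts tumour tissue could also have contributed, Col3a1 from 5.62 ± 3.80 to 266 ± 109.8, Col5a1 from 0.922 ± 0.480 to 22.8 ± 3.46 and Tnc from 0.146 ± 0.0995 to 19.7 ± 7.59. The median of the 38 such transcripts was 26.7 to 33.3 FPKM in MacB2-3wk libraries, and whether tumour tissue added to the cell cycle, glycolysis and matrix remodelling rises was not tested. Markers of some other lung cells fell in the same libraries, with 6 of 16 endothelial genes (adjusted p = 2.60e-05, but adjusted p = 0.376 with an estimated correlation) and 4 of 17 epithelial genes, while 2 epithelial genes rose (adjusted p = 0.0296, but adjusted p = 0.516 with an estimated correlation). Without MacB2-N replicate 3 the change of the mean went from -1.37 to -0.81 for endothelial and from -0.79 to -0.52 for epithelial genes. In the fibroblast list 6 of 15 members rose and 3 fell, and the list was not called (adjusted p = 0.0559). Cx3cr1 fell from 107 ± 6.47 to 35.0 ± 5.23 FPKM (-1.59) and Csf1r from 523 ± 58.8 to 222 ± 47.1 (-1.25). Ccr2 was at 229 ± 75.4 and 115 ± 17.8 FPKM and Fcgr1 at 73.2 ± 15.4 and 83.1 ± 7.53. Quantile normalization changed the split to 1374 risen and 1234 fallen, and 1680 genes passed when only these 2 groups were fitted, which lost the calls of Rny1, Scgb3a2 and Hba-a2.

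**Figure D4:**
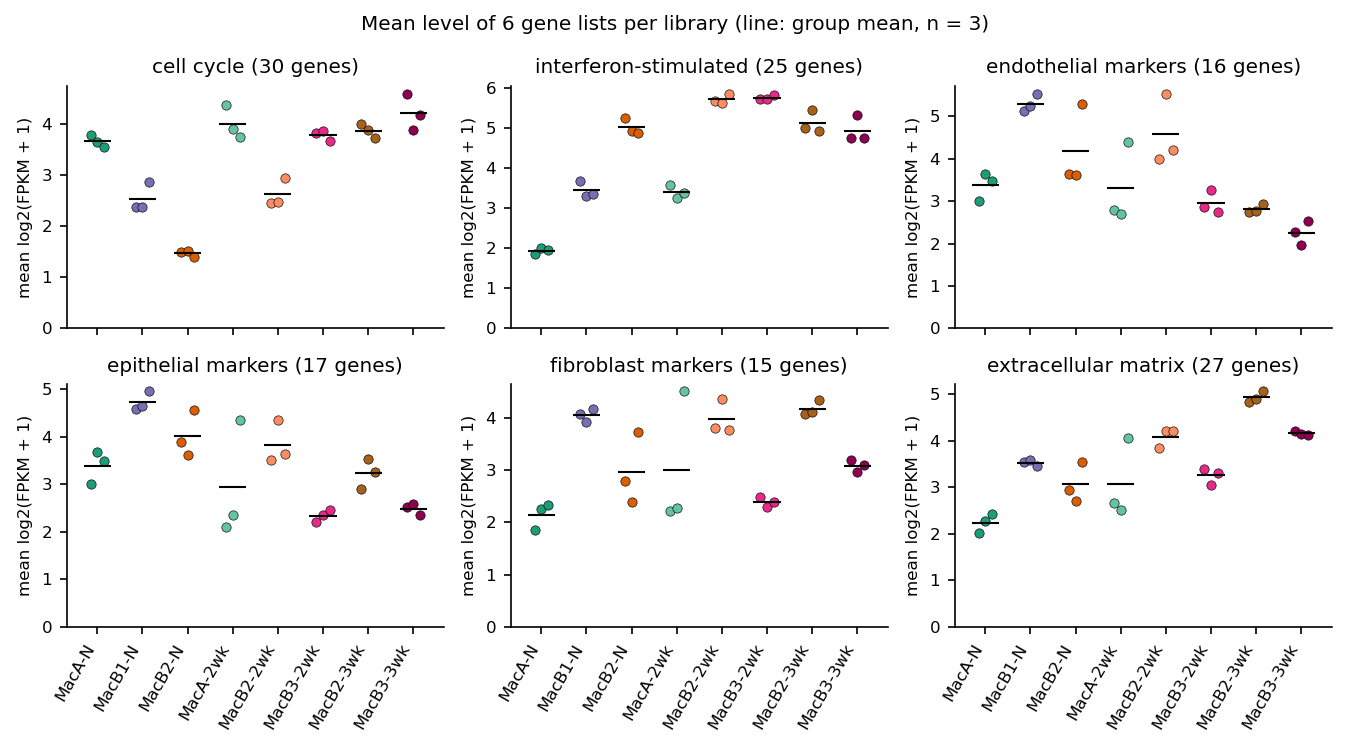
Mean log2(FPKM + 1) over the measured members of 6 gene lists in each library, with points as libraries and lines as group means. The cell cycle mean was 1.39 to 1.52 in MacB2-N and 3.74 to 4.00 in MacB2-3wk.

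MacB2-3wk was set against MacB2-2wk to ask what differed between the weeks. In MacB2-3wk 525 genes rose and 219 fell. Ptn rose from 13.1 ± 1.63 to 151 ± 24.2 FPKM (log2 fold change 3.42), the collagen gene Col16a1 from 5.07 ± 4.19 to 60.1 ± 9.02 (3.58), the matrix proteoglycan gene Dcn from 37.1 ± 14.6 to 237 ± 89.9 (2.65), Tpm2 from 4.56 ± 1.16 to 36.5 ± 11.7 (2.73), Hells from 5.95 ± 3.34 to 59.7 ± 40.2 (3.02) and the noncoding gene Dnm3os from 1.19 ± 1.40 to 20.9 ± 23.2 (2.97). Tmem100 fell from 24.2 ± 16.0 to 1.91 ± 0.375 FPKM (-2.94), the tight junction gene Cldn5 from 42.01 ± 29.2 to 4.93 ± 0.167 (-2.65), and Inmt (-2.80), Limch1 (-2.80), Tspan7 (-2.78) and Fmo1 (-2.77) also fell. The calls of Hells (adjusted p 0.00764 to 0.0889 over the alternatives, limma), Dnm3os (0.00844 to 0.172), Dcn (0.00252 to 0.0836), Cldn5 (0.00320 to 0.0978), Inmt (0.00412 to 0.114), Tspan7 (0.00352 to 0.139) and Fmo1 (0.01002 to 0.179) were lost without MacB2-2wk replicate 2, whose mean over the endothelial list was 5.52 against 4.00 and 4.22. Each of these calls was lost without 2 to 5 of the 6 libraries in turn. Without MacB2-3wk replicate 1 the call of Tpm2 was lost (adjusted p 0.00647 to 0.129 over the alternatives, limma). Ptn, Col16a1, Dcn and Tpm2 were among 38 transcripts that tumour tissue could have contributed. The 38 had a median of 5.61 to 7.80 FPKM at 2 weeks and 26.7 to 33.3 at 3 weeks. Tumour tissue was not tested as a source of the cell cycle and glycolysis rises.

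In the cell cycle list 17 of 30 measured members rose, 0 fell and 13 were not called (22 and 0 adjusted over the list alone), with adjusted p = 2.17e-17, but adjusted p = 0.0529 with an estimated correlation. Top2a rose by 2.06, Mcm3 by 1.37, Mcm6 by 1.48 and Mcm2 by 1.43 on the log2 scale. Endothelial genes fell (10 of 16, adjusted p = 8.59e-11, but adjusted p = 0.133 with an estimated correlation). Calcrl went from 409 ± 252 to 78.9 ± 1.26 FPKM, Tek from 7.46 ± 4.57 to 0.797 ± 0.312 and Eng from 74.5 ± 39.9 to 25.1 ± 2.83, and without MacB2-2wk replicate 2 or MacB2-3wk replicate 1 the calls of Tek (adjusted p 0.00364 to 0.0890 over the alternatives, limma) and Eng (0.00532 to 0.137) were lost, Eng also without MacB2-3wk replicate 2 or 3. Nonclassical monocyte genes fell (5 of 14, adjusted p = 4.18e-08, but adjusted p = 0.0529 with an estimated correlation). Emr4 (log2 fold change -1.73), Cd300e (-1.79), Ace (-1.71) and the integrin gene Itgal (-1.18) were examples. Interferon-stimulated genes fell (2 of 25, adjusted p = 8.49e-07, but adjusted p = 0.118 with an estimated correlation). An example was Cxcl9, which went from 59.0 ± 3.92 to 22.3 ± 8.86 FPKM. Glycolysis and hypoxia genes rose (3 of 25, adjusted p = 1.42e-07, but adjusted p = 0.0664 with an estimated correlation). Examples included Ero1l (1.23) and Bnip3 (1.55, lost without 4 of the 6 libraries in turn, MacB2-2wk replicate 2 among them, adjusted p 0.00126 to 0.241 over the alternatives by limma). Arg1 was at 93.3 ± 47.0 and 237 ± 65.1 FPKM and was not called. When only these 2 groups were fitted 208 genes passed, every call named here was lost but those of Ptn, Tpm2, Top2a, Mcm3, Emr4, Cd300e and Itgal, and with a pseudocount of 0.1 FPKM 493 passed.

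MacB3-2wk was set against MacB2-2wk to ask what separated the CD64 high, CD11c+ population from the CD11c- one in lungs with a tumour. MacB3-2wk had 541 genes higher and 722 lower. C1qa was at 1864 ± 122 FPKM against 71.5 ± 12.1 (log2 fold change 4.70), C1qc at 1252 ± 78.7 against 56.8 ± 17.5 (4.48) and C1qb at 2511 ± 266 against 131 ± 30.0 (4.27). Fcrls, an Fc receptor-like gene (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), was at 229.7 ± 24.3 FPKM against 4.94 ± 2.58 (5.36), Cd72 at 482 ± 118 against 22.3 ± 11.8 (4.46) and the chemokine gene Ccl12 at 302 ± 21.1 against 12.8 ± 9.19 (4.65, lost with a pseudocount of 0.1 FPKM, adjusted p 5.31e-05 to 0.0722 over the alternatives by limma). Serpinb10 (1.73 ± 0.813 against 109.9 ± 24.4, -5.37), Cd177 (-4.65), Serpinb2 (20.1 ± 13.3 against 393 ± 107, -4.37), Pglyrp1 (-4.16) and the haptoglobin gene Hp (15.1 ± 4.25 against 264 ± 11.6, -4.08) were among the lowest.

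In the lysosome list 15 of 30 measured members were higher, 0 lower and 15 not called (16 and 0 adjusted over the list alone), with adjusted p = 1.71e-17, and adjusted p = 0.0165 with an estimated correlation. Ctsb was at 915 ± 35.1 FPKM against 322 ± 33.2, Ctsd at 1037 ± 126 against 243 ± 11.5 and Lgmn at 648 ± 29.4 against 121 ± 27.7. Cell cycle genes were higher (17 of 30, adjusted p = 9.32e-16, and adjusted p = 0.0177 with an estimated correlation). Top2a (log2 fold change 1.92), Mcm3 (1.58), Mcm5 (1.25) and Mcm6 (1.40) were examples. Chemokine genes were higher (12 of 23, adjusted p = 9.78e-14, and adjusted p = 0.00331 with an estimated correlation). Cxcl16 was at 216 ± 8.55 against 30.2 ± 1.34 FPKM, Pf4 at 806 ± 370.5 against 49.3 ± 19.1 and Cxcl9 at 233 ± 11.1 against 59.0 ± 3.92. Interstitial and monocyte-derived macrophage genes were higher (10 of 17, adjusted p = 2.09e-11, and adjusted p = 0.00331 with an estimated correlation). Classical monocyte genes were lower (9 of 12, adjusted p = 2.06e-10, and adjusted p = 0.00331 with an estimated correlation). Examples included Plac8 (-2.30) and Gsr (-2.45).

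Arg1 was higher in MacB3-2wk at 570.1 ± 95.9 against 93.3 ± 47.0 FPKM (log2 fold change 2.72), as was Itgax (2.56), while Ccr2 was lower at 96.3 ± 5.95 against 223 ± 2.74 FPKM. Fcgr1 was at 181 ± 6.86 and 98.8 ± 16.3 FPKM, with an adjusted p of 0.00170 (limma) and a fold below the minimum for a call. Markers of other cell types were lower in MacB3-2wk, with 9 of 16 endothelial genes (adjusted p = 7.34e-07, but adjusted p = 0.215 with an estimated correlation), 6 of 15 fibroblast genes (adjusted p = 2.57e-06, but adjusted p = 0.194 with an estimated correlation) and 5 of 17 epithelial genes (adjusted p = 6.45e-06, but adjusted p = 0.158 with an estimated correlation). Quantile normalization changed the split to 676 higher and 527 lower, and 648 genes passed when only these 2 groups were fitted.

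MacB3-3wk was set against MacB2-3wk to ask the same at 3 weeks. MacB3-3wk had 277 genes higher and 176 lower. Fcrls was at 301 ± 19.3 FPKM against 18.8 ± 14.7 (log2 fold change 4.20), C1qa at 2048 ± 66.2 against 173 ± 30.9 (3.57), C1qc at 1440 ± 123 against 119.7 ± 22.5 (3.59), Cd72 at 438 ± 36.4 against 36.6 ± 7.56 (3.56), Klrb1b at 78.3 ± 46.9 against 4.52 ± 3.37 (3.83) and Ccl12 at 226 ± 22.8 against 17.996 ± 6.18 (3.63). Serpinb10 (-4.24), Cd177 (-3.95), Serpinb2 (-3.93), Ifitm6 (18.6 ± 7.77 against 281 ± 23.8, -3.93) and Plac8 (28.4 ± 7.21 against 366 ± 73.3, -3.66) were lower.

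In the lysosome list 13 of 30 measured members were higher, 0 lower and 17 not called (14 and 0 adjusted over the list alone), with adjusted p = 6.56e-25, and adjusted p = 0.00669 with an estimated correlation, and Lgmn (2.03), Ctsb (1.50) and Hexa (1.31) were examples. Genes of MHC class II presentation were higher (8 of 14, adjusted p = 1.44e-11, and adjusted p = 0.0165 with an estimated correlation). H2-Ab1 was at 3017 ± 474 against 676 ± 53.9 FPKM, H2-Eb1 at 1282 ± 268 against 212 ± 4.57 and the protease gene Ctss at 1571 ± 195 against 636 ± 49.2. Classical monocyte genes were lower (7 of 12, adjusted p = 1.28e-15, and adjusted p = 3.99e-04 with an estimated correlation). Examples included Hp (-3.48) and Gsr (-1.78). Chemokine genes were higher (6 of 23, adjusted p = 1.39e-07, and adjusted p = 0.0165 with an estimated correlation). Cxcl16 (log2 fold change 2.81), Pf4 (2.99), Ccl8 (3.08) and Cxcl9 (2.32) were examples. Cx3cr1 was higher (98.0 ± 14.4 against 35.0 ± 5.23 FPKM) and Ccr2 lower (55.5 ± 5.47 against 115 ± 17.8). Arg1 was at 465 ± 164 and 237 ± 65.1 FPKM and was not called. Fibroblast genes were lower as a list with no member called (adjusted p = 1.73e-05, but adjusted p = 0.302 with an estimated correlation). Without MacB3-3wk replicate 3 the count was 297 and the calls of Ccl12 (adjusted p 3.36e-04 to 0.314 over the alternatives, limma), Ccl8 (3.48e-04 to 0.228) and Ccr2 (0.00850 to 0.0902) were lost, each of them without 3 or 4 of the 6 libraries in turn. With array weights 376 genes were higher and 445 lower. The calls of Klrb1b and Ccl8 were lost when only these 2 groups were fitted.

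The genes that separated MacB3 from MacB2 overlapped between weeks, in comparisons that shared no library. Of 541 genes higher in MacB3 at 2 weeks and 277 at 3 weeks, 198 were shared, against 8.73 if the 2 sets were independent. Of 722 and 176 lower genes, 123 were shared, against 7.41. No gene was called in opposite directions, and a difference between the weeks was not tested.

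MacB3-3wk was set against MacB3-2wk to ask what differed in MacB3 between the weeks. In MacB3-3wk 48 genes rose and 6 fell. Ptn rose from 6.28 ± 2.89 to 70.1 ± 15.4 FPKM (log2 fold change 3.34), Dcn from 9.35 ± 5.21 to 94.7 ± 41.3 (3.27), Prg4 from 5.44 ± 2.24 to 69.0 ± 65.3 (3.10), Cdc42ep5 from 1.40 ± 1.79 to 20.6 ± 1.33 (3.44), the filamin gene Flnc from 5.48 ± 3.94 to 36.0 ± 2.93 (2.68) and the procollagen protease gene Bmp1 from 3.00 ± 1.30 to 23.1 ± 2.52 (2.64). Plac8 fell from 146 ± 19.02 to 28.4 ± 7.21 FPKM (-2.35), Slamf8 from 26.2 ± 4.62 to 10.6 ± 3.96 (-1.28) and the chemokine gene Cxcl13 from 15.2 ± 8.57 to 2.26 ± 1.75 (-2.32). In the interferon-stimulated list 0 of 25 measured members rose, 1 fell and 24 were not called (0 and 7 adjusted over the list alone), with adjusted p = 7.13e-23, and adjusted p = 0.0123 with an estimated correlation. Its members Gbp2 (67.8 ± 11.1 and 37.7 ± 8.07 FPKM), Oas3 (30.4 ± 0.318 and 15.1 ± 6.41), Xaf1 (35.4 ± 4.74 and 15.9 ± 4.73) and Cxcl10 (1338 ± 172 and 663 ± 168) were not called over all genes. Extracellular matrix genes rose as a list (2 of 27 members, adjusted p = 2.15e-07, but adjusted p = 0.196 with an estimated correlation). An example was Col5a1 (1.96). Fibroblast genes rose as a list with 1 of 15 members called (adjusted p = 0.0155, but adjusted p = 0.533 with an estimated correlation). Tumour tissue could have contributed the transcripts of Ptn, Dcn, Flnc and Col5a1, which were on the list of 38 such genes. Genes of MHC class II presentation fell as a list with no member called (adjusted p = 1.04e-06, but adjusted p = 0.122 with an estimated correlation), and endothelial genes did the same (adjusted p = 4.08e-05, but adjusted p = 0.378 with an estimated correlation). The count of 54 was unstable, at 11 without MacB3-2wk replicate 2 and 328 with array weights. When only these 2 groups were fitted 26 genes passed and every call named here was lost. Ptn (adjusted p 1.97e-05 to 0.0624 over the alternatives, limma) and Plac8 (1.72e-04 to 0.129, lost also with a pseudocount of 0.1 FPKM) passed whichever single library was left out. Cdc42ep5 (adjusted p 0.00180 to 0.192 over the alternatives, limma), Dcn (9.49e-04 to 0.196), Prg4 (0.00943 to 0.214), Flnc (9.53e-04 to 0.228), Bmp1 (2.91e-04 to 0.211), Col5a1 (9.67e-04 to 0.191), Slamf8 (0.00311 to 0.195) and Cxcl13 (0.00468 to 0.290) did not pass without MacB3-2wk replicate 2 or, in turn, 2 to 5 other libraries, while quantile normalization gave 21 risen and 6 fallen.

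MacB3-2wk was set against MacA-2wk to compare the CD11c+ populations of the tumour-bearing lung. MacB3-2wk had 1235 genes higher and 1249 lower. Cd72 was at 482 ± 118 FPKM against 3.12 ± 2.89 (log2 fold change 7.09), Ccl12 at 302 ± 21.1 against 4.99 ± 7.71 (6.58), Aif1 at 452 ± 28.4 against 5.33 ± 2.77 (6.28), and Fcrls (6.23), Ms4a4c (6.13) and C1qb (6.04) were also higher. Fabp1 (0.125 ± 0.217 against 295 ± 96.2, -7.99), Chil3, which encodes a chitinase-like protein (22.7 ± 4.75 against 3892 ± 113, -7.38), Plet1 (-7.36), Krt19 (-7.08), Ear1 (-7.44) and Ear2 (-7.03) were the lowest.

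All 20 of 20 measured alveolar macrophage genes were lower (adjusted p = 4.83e-26, and adjusted p = 0.00293 with an estimated correlation). An example was the cytokine gene Il18 (3.84 ± 0.884 against 163 ± 15.8 FPKM). In the interferon-stimulated list 21 of 25 measured members were higher, 0 lower and 4 not called (22 and 0 adjusted over the list alone), with adjusted p = 4.08e-24, and adjusted p = 0.00255 with an estimated correlation. Cxcl9 was at 233 ± 11.1 FPKM against 10.7 ± 4.09, Cxcl10 at 1338 ± 172 against 73.6 ± 38.8 and Gbp2 at 67.8 ± 11.1 against 14.8 ± 1.56. Chemokine genes were higher (16 of 23, adjusted p = 2.06e-16, and adjusted p = 0.00113 with an estimated correlation). Cxcl16 (log2 fold change 4.06) and Ccl5 (4.52) were examples. Interstitial and monocyte-derived macrophage genes were higher (14 of 17, adjusted p = 5.13e-20, and adjusted p = 4.33e-04 with an estimated correlation). C1qc (log2 fold change 5.41), Cx3cr1 (4.79) and Ccr2 (4.16) were examples. Glycolysis and hypoxia genes were higher (13 of 25, adjusted p = 5.41e-12, and adjusted p = 0.0113 with an estimated correlation). The growth factor gene Vegfa was at 254 ± 87.2 against 25.9 ± 11.1 FPKM, and Ndrg1 (log2 fold change 4.66) and Bnip3 (3.57) were also higher. Arg1 was at 570.1 ± 95.9 FPKM against 13.1 ± 11.5 (log2 fold change 5.63), and Fcgr1 (2.39) and Itgam (4.10) were higher, while Itgax was lower (-1.05, lost without 3 of the 6 libraries in turn and when only these 2 groups were fitted, -0.81 without MacB3-2wk replicate 2). Lane and population were confounded, and 1634 genes passed when only these 2 groups were fitted.

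MacB3-2wk was set against MacB1-N to compare the CD11b+ and CD11c+ populations of tumour-bearing and naive lung, which differed in gate for CD64 as well as in tumour. MacB3-2wk had 1427 genes higher and 2254 lower. Arg1 was at 570.1 ± 95.9 FPKM against 0.515 ± 0.301 (log2 fold change 8.56), Ccl12 at 302 ± 21.1 against 1.53 ± 1.41 (7.11), Cxcl9 at 233 ± 11.1 against 1.62 ± 0.848 (6.53), Cxcl3 at 223 ± 94.7 against 1.39 ± 0.411 (6.46) and Pf4 at 806 ± 370.5 against 9.44 ± 4.75 (6.29). The small RNA gene U5 (ENSMUSG00000075930) was listed at 0 in all 3 MacB1-N libraries and at 236, 758 and 97.1 FPKM in MacB3-2wk, and its call was lost when any single library of these 2 groups was left out (adjusted p 0.00375 to 0.116 over the alternatives, limma). Pglyrp1 (3.72 ± 2.59 against 613 ± 228, -7.13), Eno3 (-5.74), Ear2 (-5.68), Serpinb10 (-5.59), the lectin gene Cd209a (-5.58) and the sphingolipid receptor gene S1pr5 (0.451 ± 0.154 against 68.3 ± 16.6, -5.55) were the lowest.

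In the interferon-stimulated list 22 of 25 measured members were higher, 0 lower and 3 not called (23 and 0 adjusted over the list alone), with adjusted p = 1.54e-20, and adjusted p = 0.00513 with an estimated correlation, including Cxcl10 (4.72), Isg15 (3.29) and Gbp2 (2.21). Lysosome genes were higher (23 of 30, adjusted p = 2.40e-18, and adjusted p = 0.0131 with an estimated correlation). Gpnmb was at 357 ± 20.8 against 6.13 ± 7.33 FPKM. Nonclassical monocyte genes were lower (13 of 14, adjusted p = 5.28e-13, and adjusted p = 0.00661 with an estimated correlation). Ace was at 15.2 ± 3.43 against 745 ± 158 FPKM. Matrix remodelling genes were higher (17 of 22, adjusted p = 1.12e-12, and adjusted p = 0.00422 with an estimated correlation). Mmp14 was at 222 ± 45.6 against 7.05 ± 1.05 FPKM and Tgfbi at 765 ± 119 against 80.2 ± 9.32. Glycolysis and hypoxia genes were higher (17 of 25, adjusted p = 1.42e-11, and adjusted p = 0.0131 with an estimated correlation). Fcgr1 was higher (4.11) and Itgax was at 72.3 ± 21.6 and 103 ± 11.2 FPKM. Markers of other cell types were lower in MacB3-2wk, with 16 of 16 endothelial genes (adjusted p = 5.03e-07, but adjusted p = 0.227 with an estimated correlation) and 13 of 17 epithelial genes (adjusted p = 2.52e-06, but adjusted p = 0.140 with an estimated correlation). Quantile normalization changed the split to 1839 higher and 1711 lower with a shift of 0.121 in the median.

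**Figure D5:**
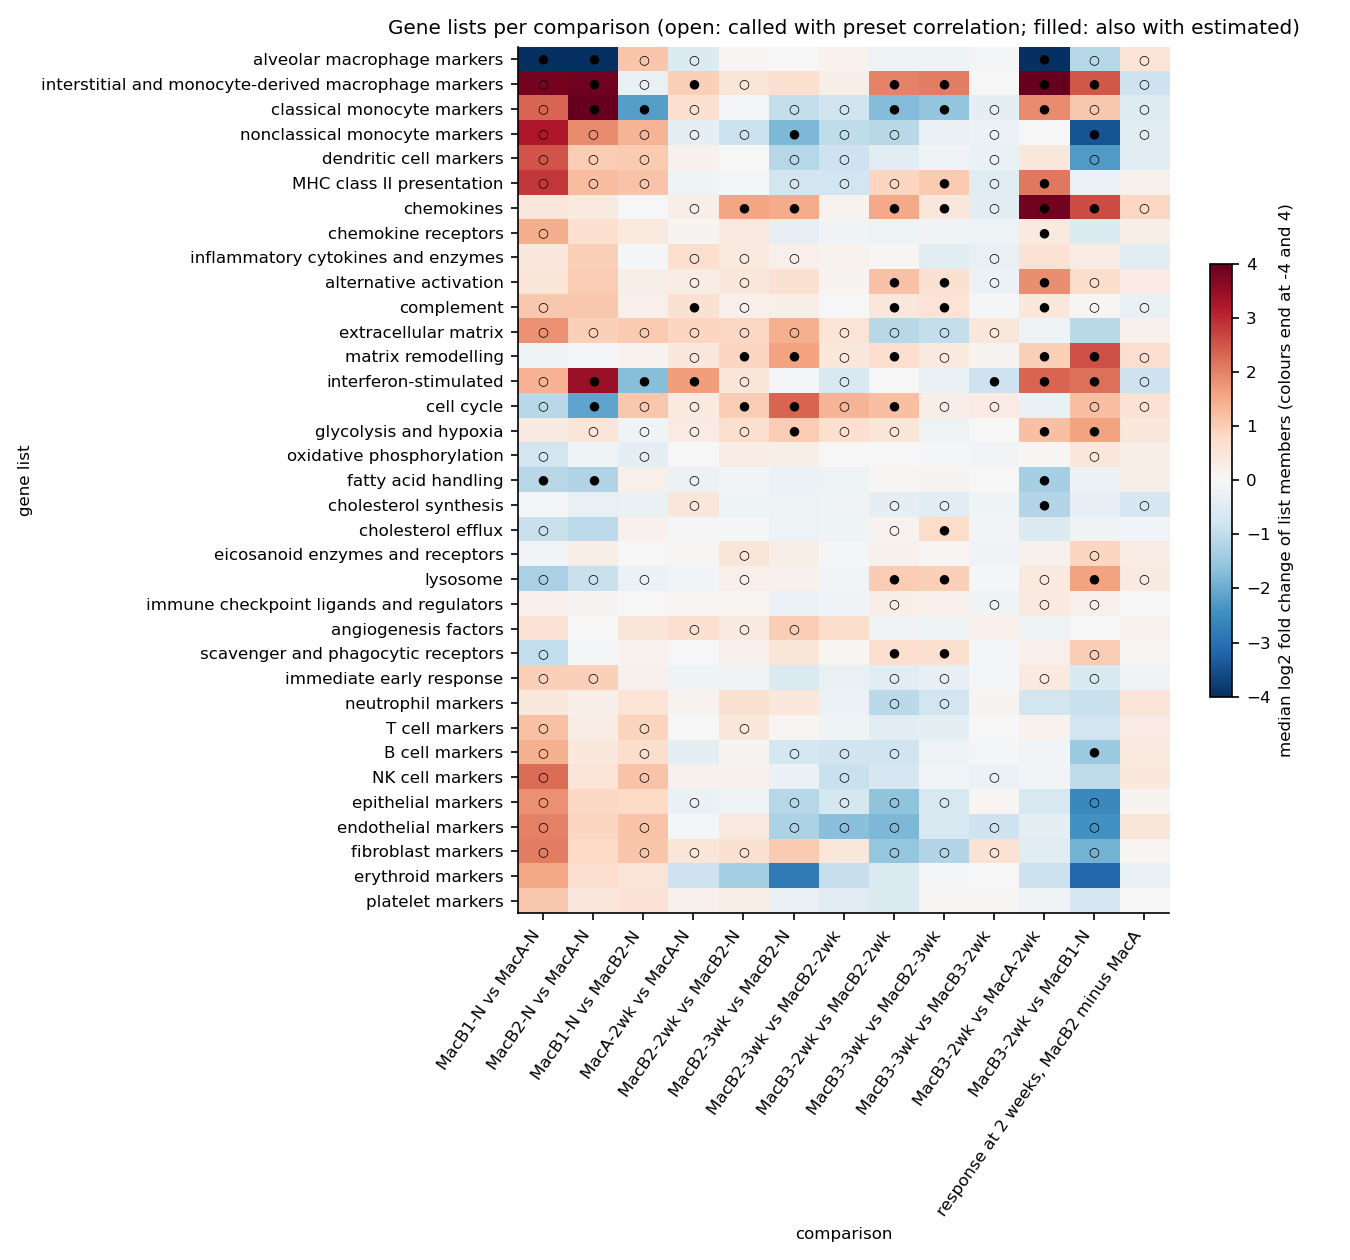
Median log2 fold change of 35 gene lists (vertical) in 13 comparisons (horizontal), with colours from -4 to 4. Open circles mark lists called with the preset correlation between genes, and filled circles those also called with an estimated correlation, 13 of them for MacB3-2wk against MacA-2wk.

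The interaction asked whether the log2 change from naive to 2 weeks differed between MacB2 and MacA. It called 38 genes, 23 with a positive difference (MacB2 minus MacA) and 15 with a negative one. Gpnmb went from 1.55 ± 0.572 to 42.5 ± 21.8 FPKM in MacB2 and from 153 ± 45.2 to 179 ± 77.3 in MacA (difference of log2 changes 3.78), and Ube2c from 1.47 ± 0.871 to 25.1 ± 6.47 and from 33.5 ± 7.84 to 45.7 ± 10.99 (3.02). Scimp (2.97), Adcy3 (2.80) and Actn1 (2.64) also had a positive difference. C1qa went from 37.8 ± 3.48 to 71.5 ± 12.1 FPKM in MacB2 and from 0.836 ± 0.442 to 39.6 ± 23.2 in MacA (-3.38), and C1qc (-3.29), Ifi27l2a (-3.16), Pla2g7 (-2.67), Oas3 (-2.60), Oasl2 (-2.39) and Itgam (-2.58) had a negative difference.

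Cell cycle genes had a positive difference as a list (1 of 30 members called, adjusted p = 1.65e-06, but adjusted p = 0.201 with an estimated correlation) and interferon-stimulated genes a negative one (2 of 25, adjusted p = 1.65e-06, but adjusted p = 0.183 with an estimated correlation). The list of interstitial and monocyte-derived macrophage genes had a negative difference (3 of 17, adjusted p = 2.08e-05, but adjusted p = 0.103 with an estimated correlation). Matrix remodelling genes (1 of 22, adjusted p = 4.64e-05, but adjusted p = 0.103 with an estimated correlation) and chemokine genes (0 of 23, adjusted p = 4.64e-05, but adjusted p = 0.103 with an estimated correlation) had positive differences. Arg1, with 93.3 ± 47.0 FPKM in MacB2-2wk and 13.1 ± 11.5 in MacA-2wk, was not called. Lane and population remained confounded, and carry-over into MacA-2wk could give the negative difference of C1qa, C1qc and Itgam. Of 100 regroupings, 5, the real one included, gave at least as many calls. Without MacA-N replicate 1 the calls of Gpnmb (adjusted p 0.0178 to 0.149 over the alternatives, limma), Pla2g7 (0.00493 to 0.302), Itgam (0.0109 to 0.302) and Oasl2 (0.0126 to 0.197) were lost, each of them without 9 to 11 of the 12 libraries in turn. The count was 13 when only these 4 groups were fitted, which lost every call named here but that of Oas3, and 17 without MacB2-2wk replicate 3.

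Some further lists were called with the correlation between genes preset and estimated. They were interstitial macrophage genes in MacB2-N against MacA-N, scavenger receptor, alternative activation and complement genes in MacB3 against MacB2 at both weeks, with matrix remodelling genes at 2 weeks and interstitial macrophage genes at 3 weeks, and interstitial macrophage, chemokine and B cell genes in MacB3-2wk against MacB1-N. In MacB3-2wk against MacA-2wk 13 of 16 lists remained, all but immune checkpoint, immediate early and lysosome genes. None remained in MacB2-3wk against MacB2-2wk or in the interaction.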

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

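The interaction was chosen before the data were examined, and the tests of carry-over, of tumour mass, of other lung cells, of the lobe and of regrouped samples were chosen only after the results were seen.

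A difference between groups, tested by the interaction, drew attention to 38 genes. Their log2 change to 2 weeks, smaller for an equal FPKM gain from a higher start, differed between MacB2 and MacA. The difference was positive for Gpnmb (3.78), Ube2c (3.02), Scimp (2.97), Adcy3 (2.80) and Actn1 (2.64). It was negative for C1qa (-3.38), C1qc (-3.29), Ifi27l2a (-3.16), Pla2g7 (-2.67), Oas3 (-2.60), Itgam (-2.58) and Oasl2 (-2.39). Of 100 regroupings of the 12 libraries, 5 gave at least as many genes, the real one included. Of the other 4, 3 swapped the 2 groups of 1 population up to 1 library on each side, with counts up to 111. They compared nearly the sum of the 2 changes and say little about chance. The remaining 1, among 51 without such a swap, exchanged 1 library between the groups of each population and gave 65. So chance cannot be excluded for the count of 38. Whether structure other than the groups added to the 111, or carry-over to the negative differences, was not tested.

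For the 12 pairwise comparisons, 10 splits of 6 libraries are too few for a share under 0.05, and the real split was the 1 with the most genes in each. Real and highest other counts were 4067 and 3 (MacB1-N against MacA-N), 3583 and 16 (MacB2-N against MacA-N), 893 and 21 (MacB1-N against MacB2-N), 135 and 7 (MacA-2wk against MacA-N), 323 and 2 (MacB2-2wk against MacB2-N) and 2524 and 2 (MacB2-3wk against MacB2-N). They were 744 and 2 (MacB2-3wk against MacB2-2wk), 1263 and 1 (MacB3-2wk against MacB2-2wk), 453 and 3 (MacB3-3wk against MacB2-3wk), 54 and 1 (MacB3-3wk against MacB3-2wk), 2484 and 10 (MacB3-2wk against MacA-2wk) and 3681 and 3 (MacB3-2wk against MacB1-N).

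The rise of genes in MacA-2wk could come from carry-over of MacB2 or MacB3 cells into the SiglecF+ gate. Genes under 1 FPKM in MacA-N and at least 50 FPKM in MacB2-2wk or MacB3-2wk, with C1qa, C1qc and Arg1 left out, set a bound on the share of such cells of 8.62%, 5.30% and 6.91% in the 3 libraries. For C1qa, C1qb, C1qc and Arg1, 0 of 4 needed more in any library, so carry-over stays open for them, beside expression by MacA cells. With the 3 genes kept the bound was 10.1%, 6.47% and 8.69%, and 5 of 14 interferon-stimulated and 63 of 107 other risen genes needed more in every library, which decides nothing, since these genes were chosen as risen. A mixture of MacA cells at their naive level with MacB cells cannot pass both. At a mean of at least 5 FPKM, 0 of the 14 lay above every MacA-N, MacB2-2wk and MacB3-2wk library in all 3 MacA-2wk libraries. Of the 107, 5 did (Slc40a1, Ppap2b, Sc5d, Ptgr1 and Tsku). These 5 were chosen as risen too, so chance and other cells stay open. For the 14 and the other 102, carry-over and a response of MacA cells cannot be told apart, since they overlapped those libraries or were near the floor. Of the 102, 7 (Col3a1, Serpinf1, Gja1, Hmga2, Ptn, Dkk2 and Flnc) were on the list of tumour-mass transcripts, so tumour tissue is open for them too. This was form 4 of the test, and form 1 had a bound of 44.7% with 0 of the 14 and 36 other genes above it. A response of MacA cells to the tumour remains a hypothesis.

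Transcripts of fibroblasts, matrix and tumour cells rose in MacB2-3wk, 27 of 38 on a list written after the data were seen and before its test, of which 15 were also on another list. Their log2 ratio of MacB3-3wk to MacB2-3wk had a median of -1.16 and an SD of 0.217, against a median SD of 0.822 (5th percentile 0.578) in 10000 level-matched sets of other risen genes. Tumour-mass cells or RNA in the sorted fractions would give such a shared ratio, but so would macrophage genes regulated together, so both stay open. Levels were 266 and 99.9 FPKM for Col3a1, 237 and 94.7 for Dcn and 151 and 70.1 for Ptn in MacB2-3wk and MacB3-3wk, and the median of the listed genes was 11.8 FPKM in MacA-2wk replicate 3 against 1.48 and 1.67 in replicates 1 and 2. Per the labels doublets and dead cells were excluded, and the CD11b+ gate would remove tumour cells and fibroblasts, leaving fragments, free RNA and missed doublets as open routes.

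Epithelial and endothelial transcripts fell in MacB2 from naive to 3 weeks. The change of the list mean was -1.37 for endothelial genes (-0.81 without MacB2-N replicate 3) and -0.79 for epithelial genes (-0.52 without it), and Scgb1a1 went from 6967 to 619 FPKM, Sftpc from 121 to 27.8, Calcrl from 257 to 78.9 and Cldn5 from 33.7 to 4.93. Of the members with at least 5 FPKM in MacB2-N, 90.9% of epithelial genes (10 of 11) and 100% of endothelial genes (16 of 16) were lower in MacB2-3wk, but this share restates the fall on members with a high start, so it decides nothing, and less RNA or fewer cells of those types in the sorted fraction stays open. Naive lungs were used whole and tumour samples came from the left lobe. MacB2-2wk, also from the left lobe, had an endothelial mean 0.39 above that of MacB2-N (standard error 0.732), at -0.08 without MacB2-2wk replicate 2 and 0.95 without MacB2-N replicate 3. From MacB2-2wk to MacB2-3wk this mean changed by -1.76 (standard error 0.478, and -1.29 without MacB2-2wk replicate 2), with libraries at 4.00 to 5.52 and at 2.75 to 2.94, which argues against the lobe as the whole cause of the endothelial fall. For epithelial genes the change from MacB2-N to MacB2-2wk was -0.18 (standard error 0.381), at -0.44 and 0.09 without these 2 libraries in turn, less than 2 standard errors from both 0 and -0.79, and the change within the left lobe was -0.61 (standard error 0.318, and -0.35 without MacB2-2wk replicate 2) with overlapping libraries, so lobe and tumour cannot be told apart there. Of the lists, 0 of 17 epithelial, 2 of 16 endothelial and 6 of 15 fibroblast genes were on another list.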

How the results depend on the processing

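The fit of protein-coding genes only was chosen after the data were seen, and the other alternatives were chosen before the data were examined. Of 458 results for named genes, 350 were called, and of their 7062 alternatives 6642 kept the direction and side of the threshold, 365 fell below it, 55 passed it and 0 reversed.

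Counts that moved by over 1.5 times are grouped by setting, and the causes were not tested. With only the groups compared, the counts were 268 for MacB1-N against MacB2-N and 4 for MacA-2wk against MacA-N. Against MacB2-N they were 37 for MacB2-2wk and 1680 for MacB2-3wk. Against MacB2-2wk they were 208 for MacB2-3wk and 648 for MacB3-2wk. They were 26 for MacB3-3wk against MacB3-2wk, 1634 for MacB3-2wk against MacA-2wk and 13 for the interaction. With a pseudocount of 0.1 FPKM they were 238 for MacA-2wk against MacA-N, 493 for MacB2-3wk against MacB2-2wk, 19 for MacB3-3wk against MacB3-2wk and 89 for the interaction. With array weights they were 205 for MacA-2wk against MacA-N, 1145 for MacB2-3wk against MacB2-2wk, 821 for MacB3-3wk against MacB2-3wk (376 higher and 445 lower, against 277 and 176), 328 for MacB3-3wk against MacB3-2wk and 58 for the interaction. For MacB3-3wk against MacB3-2wk quantile normalization gave 27 and protein-coding genes only gave 100. For the interaction no filter on low values gave 23 and the block on replicate number gave 24.

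With an estimated correlation between genes, the lists called of 35 went from 23 to 2 (MacB1-N against MacA-N), 13 to 6 (MacB2-N against MacA-N), 17 to 2 (MacB1-N against MacB2-N), 18 to 3 (MacA-2wk against MacA-N), 16 to 3 and 14 to 5 (MacB2-2wk and MacB2-3wk against MacB2-N), 13 to 0 (MacB2-3wk against MacB2-2wk), 22 to 9 and 17 to 9 (MacB3 against MacB2 at 2 and 3 weeks), 14 to 1 (MacB3-3wk against MacB3-2wk), 16 to 13 (MacB3-2wk against MacA-2wk), 22 to 8 (MacB3-2wk against MacB1-N) and 11 to 0 (interaction).

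Leaving out 1 library gave 3683 to 3899 genes for MacB1-N and 3225 to 3567 for MacB2-N against MacA-N, 2152 to 2443 for MacB2-3wk against MacB2-N, 920 to 1234 for MacB3-2wk against MacB2-2wk, 2154 to 2681 for MacB3-2wk against MacA-2wk and 3154 to 3682 for MacB3-2wk against MacB1-N. For MacB1-N against MacB2-N it gave 606 to 1393 (1393 without MacB2-N replicate 3), for MacA-2wk against MacA-N 87 to 244 (87 without MacA-N replicate 2, 244 without MacA-2wk replicate 2), for MacB2-2wk against MacB2-N 136 to 292 (204 without MacB2-N replicate 1, 136 without MacB2-2wk replicate 3), for MacB2-3wk against MacB2-2wk 449 to 753 (449 without MacB2-3wk replicate 1) and for MacB3-3wk against MacB2-3wk 297 to 384 (297 without MacB3-3wk replicate 3). For MacB3-3wk against MacB3-2wk it gave 11 to 38, with 28 and 11 without MacB3-2wk replicates 1 and 2 and 28, 18 and 29 without MacB3-3wk replicates 1, 2 and 3. For the interaction it gave 17 to 57, with 24, 19 and 22 without MacA-N replicates 1 to 3, 25 and 20 without MacB2-N replicates 1 and 2, 23 and 57 without MacA-2wk replicates 1 and 2, and 19 and 17 without MacB2-2wk replicates 1 and 3, and its lists ranged from 9 to 17 (17 without MacA-2wk replicate 3).

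Same-number MacB libraries had a mean residual correlation of 0.007 (45 pairs, highest 0.210) against -0.003 in 90 other pairs. These mixed conditions, so pairing stays open. The block changed no count but that of the interaction by over 1.5 times. Within MacB groups, 1 gene differed between lanes at an adjusted p under 0.05 by limma and 856 did before adjustment. Depth limits genes near 1 FPKM, and the relative depth of 0.521 in MacB2-2wk replicate 3 makes a value of 0 less certain there.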

Other observations

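The lists in this part were written before the data were examined, the members named here were chosen after their values were seen, and no test of an explanation was added.

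Genes of eicosanoid synthesis and sensing went both ways between populations. Ltc4s, which encodes leukotriene C4 synthase, was at 404 ± 34.6 FPKM in MacA-N and 2.72 ± 2.54 in MacB2-N, and Alox5 was at 133 ± 6.20 and 8.31 ± 3.41. Ptgs2, which encodes an inducible cyclooxygenase, was higher in MacB2-N at 96.9 ± 15.5 against 4.49 ± 2.39 FPKM (log2 fold change 4.23). In MacB2-3wk against MacB2-N the prostaglandin E synthase gene Ptges rose from 6.64 ± 3.06 to 99.7 ± 26.2 FPKM (3.78), and Hpgd, whose product degrades prostaglandins, fell from 136 ± 13.5 to 16.7 ± 2.54 (-2.95). As a list, 1 of 21 members rose in MacB2-2wk against MacB2-N (adjusted p = 0.0364, but adjusted p = 0.148 with an estimated correlation).

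Immune checkpoint ligands and regulators were higher as a list in MacB3-2wk against MacA-2wk, with 8 of 17 higher and 1 lower (adjusted p = 0.00267, but adjusted p = 0.170 with an estimated correlation). Tnfrsf14 (223 ± 19.5 against 9.20 ± 9.22 FPKM), Cd86 (112 ± 9.73 against 22.3 ± 6.67) and Il10 (8.12 ± 2.75 against 1.38 ± 1.33) were higher, and Cd47 was lower (39.3 ± 0.930 against 145 ± 15.1).

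Cholesterol synthesis genes were lower in MacB3-2wk than in MacA-2wk, with 12 of 18 lower (adjusted p = 1.97e-06, and adjusted p = 0.0126 with an estimated correlation), including Lss (-2.33), Hsd17b7 (-2.20) and Sqle (-1.44). Cholesterol efflux genes were higher in MacB3-3wk than in MacB2-3wk, with 2 of 13 higher (adjusted p = 0.00338, and adjusted p = 0.0300 with an estimated correlation), namely Apoe (7234 ± 1503 against 1154 ± 366 FPKM, 2.67) and the sterol transporter gene Abca1 (39.0 ± 5.83 against 17.3 ± 2.36, 1.13).

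Gapdh was at 14.6 to 40.7 FPKM and Actb at 8302 to 16107 over the 24 libraries, while Alox5ap reached 16194 to 78800. Reads were not analysed here, so whether these values belong to the identifiers in their rows, or include reads shared with other loci, was not checked.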
